A study of Mus musculus with 4 samples.

How the data were processed

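Total RNA was extracted with trizol from livers perfused with PBS, per the labels' protocols. Lysate of 6 mice per group was pooled and split into 2 technical replicates, and libraries were made from 200 ng of total RNA with the KAPA HyperPrep RNA kit (per the labels' protocols). Adapter trimming with Trim Galore 0.4.5 and cutadapt 1.18, quality control with FastQC 0.11.9, alignment with HISAT2 2.1.0, file handling with SAMtools 1.9 and the builds GRCm38 and mm10 are named per the submitters' processing notes, which give no order or settings. The counting tool, its annotation release and its strand setting are not given in the sources used here. The authors deposited 1 table of raw counts per library, with 43432 Ensembl gene identifiers each. The authors also deposited a TPM table (counts divided by gene length and scaled to a common total) of the 4 libraries, mapped by column names to the samples. Within it, the ratio of count to TPM of a gene differed between columns by at most 0.0749% after scaling, so it holds the same counts divided by gene length. The deposited counts, not the TPM values, entered the main test.

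Gene names, positions, biotypes, exons and strands came from GENCODE mouse release M21 on GRCm38, the build the processing notes name; 42548 identifiers matched and 884 did not, and the latter kept their identifiers. A gene was said to have an opposite-strand exon when an annotated exon of another gene on the other strand overlapped one of its own by at least 1 base: this held for 6940 genes and not for 35608. The share of each gene's 50-base exon words that also occur in another gene was computed, and genes with a high share are given as uncertain, since reads of near-identical copies cannot be assigned. Where counting does not use strand, reads of overlapping genes cannot be told apart either. The level predicted from the opposite strand was the mean WT_chow CPM of each overlapping gene times the overlapped share of its exon length, summed over partners.

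Groups followed the labels: WT_chow (chow) and NASH_GAN (GAN), with 2 libraries each. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), scaled with TMM, and tested with a robust quasi-likelihood fit without covariates on 2 residual degrees of freedom, in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size. Standard errors were taken from the log2 change and the F statistic. In simulated data for this comparison, with 200 of 16353 genes changed, 38.8% of 2-fold changes, 100% of 4-fold changes and 100% of 8-fold changes were called, with 4 calls among 14309 unchanged genes tested. The changed genes were drawn only from those with higher WT_chow levels, and both simulated groups had WT_chow proportions. These rates therefore do not cover genes with low counts or groups whose counts lie on different genes, as here. CPM values are counts over the library's total, and levels are given as mean ± SD over the 2 libraries of a pool. Where a group had no counts, a fold was computed against a floor of 3 counts over that group, and with 1 to 3 counts the ratio is given with an exact 95% binomial interval. These folds and ratios use library totals, not the TMM scale of the calls, on which falls in NASH_GAN are smaller. A bound under 2-fold does not itself show a 2-fold change, and calls at 0 counts rest on fitted values. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

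The 36 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest log2 changes among called genes with a mean of at least 5 CPM and separated libraries, leaving out gene models without a curated symbol; up to 4 called members per list with a mean of at least 1 CPM; and a panel of markers. A list's median log2 change was set beside 10000 random lists of the same size matched on mean expression in 20 bins, and was said to stand apart below percentile 2.5 or above 97.5. No p-value was computed for lists, since each group is 1 pool. Medians with members at 0 in NASH_GAN set to their bound used the same floor of 3 counts over the group on the TMM scale; percentiles at the bound, with all libraries or without 1, were added after the data were seen and set such genes to their bound in the random lists as well.

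To compare the replicates of a pool, counts on genes whose predicted opposite-strand level came to at least 90% from 1 transcribed gene were summed per transcribed gene, with at least 20 counts in NASH_GAN, leaving out mitochondrial genes. Lists were grouped as hepatocyte (10 lists) or non-hepatocyte (13 lists), a grouping written after the data were seen, and differences between the groups were tested by permutation with 100000 resamples. The WT_chow libraries were also thinned to the depths of the NASH_GAN libraries in 20 draws. Alternatives were DESeq2 1.42.0 size factors, upper quartile and total count scaling, TMM without the 50 most counted and mitochondrial genes, other filters, the DESeq2 Wald test, a replicate block, each library left out, other fold floors, genes with a count in every library, and limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1). Fits on genes with and without an opposite-strand exon were added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.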

Results

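Read counts per gene were compared between whole livers of C57BL/6NTac mice fed chow (WT_chow) and whole livers of mice labelled NASH and given a diet labelled GAN (NASH_GAN). NASH stands for nonalcoholic steatohepatitis, a fatty liver disease with inflammation and scarring. The labels do not expand GAN, which is in common use as the name of a NASH-inducing diet rich in fat, fructose and cholesterol. Each group was 1 pool of liver lysate from 6 mice, split into 2 technical replicates, so the 4 libraries stand for 2 pools. All p-values therefore measure the technical spread between libraries of a pool, and a difference between groups is a difference between these 2 pools. The question the labels give is how NASH liver differs from wild-type liver, with macrophages and hepatic stellate cells named in the series title. WT_chow libraries held 29734184 and 29421255 counts over genes, and NASH_GAN libraries held 1170580 and 823388. A count was present for 22771 and 22878 genes in WT_chow and for 15200 and 10436 genes in NASH_GAN. A floor of 3 counts over a group corresponded to 0.0507 CPM (counts scaled to a common library total) in WT_chow and 1.505 CPM in NASH_GAN.

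The deposited counts of the groups lay on different genes. In WT_chow the most counted gene was Alb, which encodes albumin, the main plasma protein made by hepatocytes, with 9.10% and 7.98% of counts. In NASH_GAN Alb held 0.101% and 0.115%, and the most counted gene was mt-Nd6, a subunit of mitochondrial complex I, with 10.6% in each library. Genes with an annotated exon overlapped by an exon of another gene on the opposite strand held 21.5% and 22.2% of WT_chow counts and 74.4% and 78.2% of NASH_GAN counts. Genes without such an overlap held 78.4% and 77.8% in WT_chow against 12.5% and 7.45% in NASH_GAN. The Wilson 95% interval of each share in this paragraph reached at most 0.0892 percentage points to either side. Of the 25 most counted genes of NASH_GAN, 22 had an opposite-strand exon and 3 were identifiers absent from the annotation used. Those 3 had 0 counts in both WT_chow libraries. All identifiers absent from the annotation held 13.1% and 14.4% of NASH_GAN counts, against 0.0827% and 0.0811% of WT_chow counts, and their strand and position are not known here. B430119L08Rik, an antisense transcript at chromosome 12, 103895897 to 103898784 (GRCm38, plus strand), had 32300 and 67295 counts in NASH_GAN against 349 and 383 in WT_chow, and its exons overlap those of Serpina1c by 429 bases. Gm30097, a long noncoding RNA at chromosome 3, 82926665 to 83008488 (minus strand), had 16155 and 21743 counts against 16 and 1, and it overlaps Fgg, which encodes the fibrinogen gamma chain, by 115 bases. Gm15883, antisense to the periportal cytochrome gene Cyp2f2 at chromosome 7, 27124481 to 27130674, had 5214 and 16339 counts against 280 and 397. Gm15622, antisense to Bhmt at chromosome 13, 93625382 to 93628633, had 4650 and 9265 counts against 48 and 50. These 4 transcripts were chosen after their values were seen.

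Across 5835 genes with an opposite-strand exon of a gene counted in WT_chow, the NASH_GAN level followed the opposite gene rather than the gene itself. Spearman's rho between the NASH_GAN level and the level predicted from the opposite gene in WT_chow was 0.66 in replicate 1 and 0.67 in replicate 2. With the gene's own WT_chow level it was 0.16 and 0.17. In WT_chow the rho with the opposite gene was 0.18 and 0.19, and between the libraries themselves it was 0.99. These are correlations across genes, which are not independent replicates.

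**Figure D1:**
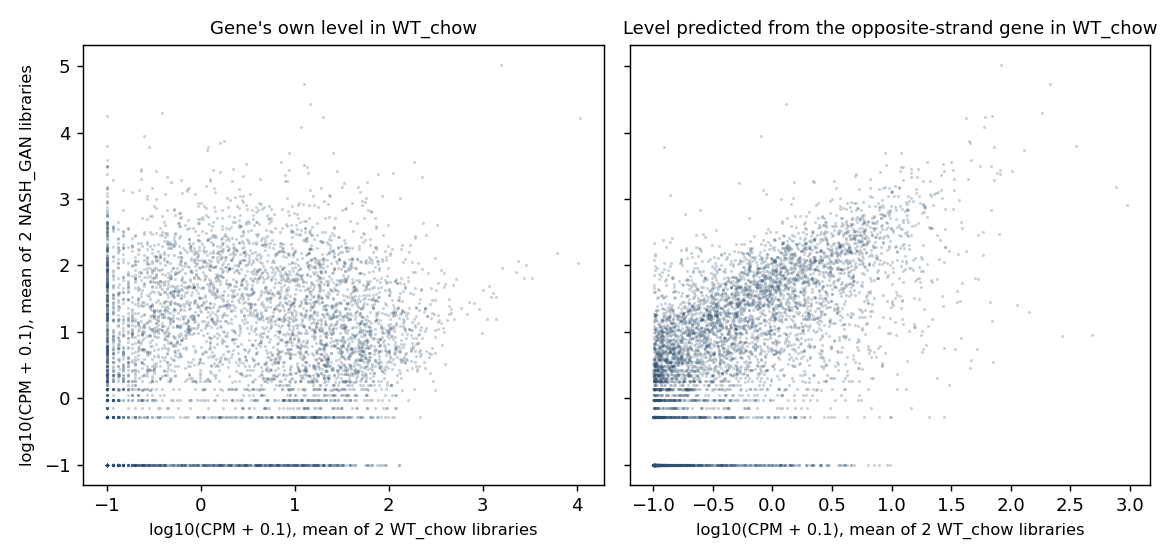
Each point is 1 of 5835 genes with an opposite-strand exon, with log10(CPM + 0.1) in NASH_GAN (mean of 2 libraries) on the vertical axis, against the gene's own WT_chow level (left) and against the level predicted from the opposite-strand gene in WT_chow (right). The points follow the prediction on the right (rho 0.66 and 0.67 per library) more closely than the own level on the left (0.16 and 0.17).

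Protein genes of the mitochondrial genome differed by strand, with exceptions. Its 12 protein genes on the plus strand, which include the cytochrome oxidase gene mt-Co1 and the cytochrome b gene mt-Cytb, held 7.28% and 9.58% of WT_chow counts and 3.74% and 0.466% of NASH_GAN counts. The single protein gene on the minus strand, mt-Nd6 (positions 13552 to 14070), held 0.174% and 0.140% in WT_chow and 10.6% in each NASH_GAN library. The plus-strand gene mt-Nd5, whose exon overlaps that of mt-Nd6 by 14 bases, went the other way in NASH_GAN replicate 1, with 29865 CPM against 9549 and 12135 in WT_chow, but not in replicate 2 (3937 CPM). All 11 tested mitochondrial transfer RNA genes were counted higher, on either strand, among them plus-strand mt-Tt with 44 and 57 counts against 0 and 0. The largest counts in replicate 1 were on the minus strand (mt-Te 5635, mt-Tp 3172), and the largest on the plus strand was 144 (mt-Tm). Some minus-strand genes were lower than this, such as mt-Tn with 32 in replicate 1 and mt-Ts1 with 16 in replicate 2. For mt-Nd6 the log2 change was 6.67 ± 0.48 (SE; edgeR adjusted p = 7.8e-05). Of the 12 measured mitochondrially encoded protein genes, mt-Nd6 was counted higher, 4 were counted lower and 7 did not pass, with a median log2 change of -2.80 (percentile 24.9, or 13.8 with genes at 0 in the matched lists at their bound). The lower ones included mt-Nd1, at 10210.2 ± 1637 CPM in WT_chow and 579 ± 574 CPM in NASH_GAN (SD, n = 2 libraries), and mt-Co1, at 34916 ± 7054 against 689 ± 818 CPM. The level of mt-Co1 and mt-Co2 is uncertain, because 51.1% and 100% of their 50-base words also occur in another gene. The call of mt-Co2 was lost without WT_chow replicate 2 (adjusted p = 0.099) and without NASH_GAN replicate 1 (0.32) or 2 (0.35). The list median was -1.55 without WT_chow replicate 2 and -6.19 without NASH_GAN replicate 1, or -4.66 at the bound. Without WT_chow replicate 1 it lay at percentile 1.03 at the bound.

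**Figure D2:**
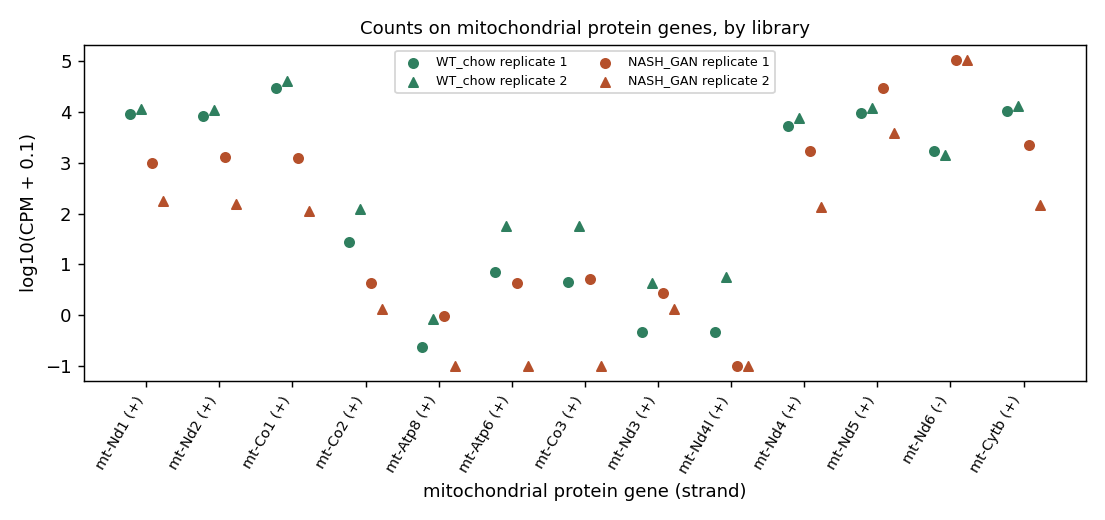
Points give log10(CPM + 0.1) of each of the 13 mitochondrial protein genes in each library, ordered by position, with the strand in brackets. Gene mt-Nd6, the one gene on the minus strand, lies above WT_chow in both NASH_GAN libraries (106160 and 105833 CPM against 1737 and 1399).

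Between NASH_GAN and WT_chow, 4304 genes were counted higher and 8204 lower among 16353 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change), and 3845 were not called. The median log2 change over all tested genes was -2.50, or -1.12 with genes at 0 in NASH_GAN set to their bound, so a list with a median near that value did not stand apart from other genes. Other scalings shifted this median by -0.37 (DESeq2 size factors), 0.93 (upper quartile) and -0.56 (total counts), and without NASH_GAN replicate 1 it was -4.87, or -1.11 at the bound; at the bound without NASH_GAN replicate 2 it was -0.68. Of 4967 tested genes with an opposite-strand exon, 2509 were higher and 1502 lower (median log2 change 1.41). Of 11248 without one, 1742 were higher and 6658 lower (median -3.51). The balance differed in separate fits of each set, where scale factors and dispersions were estimated anew: the former gave 1817 higher and 2453 lower (median -1.20) and the latter 1940 higher and 4047 lower (median -2.26). Among the latter, 72.5% of the higher genes lay inside or within 5 kb of an opposite-strand gene of at least 5 CPM in WT_chow, against 20.1% of those not higher (odds ratio 10.5, 95% interval 9.31 to 11.8, across genes). Of 1021 tested transcripts annotated as antisense, 957 were higher and 10 lower, while of 12982 protein-coding genes 2074 were higher and 7831 lower. Tested genes at 0 in both NASH_GAN libraries numbered 3341, and 257 were at 0 in both WT_chow libraries. Leaving out a WT_chow library lowered the count of lower genes to 4476 (without replicate 1) and 4569 (without replicate 2). More named genes lost their call then than without a NASH_GAN replicate. Each such fit takes its spread from the group with 2 libraries left. The NASH_GAN pair varied more, with a coefficient of variation of 44.3% against 16.2% for the WT_chow pair. The difference in lost calls therefore does not show that calls are robust to the NASH_GAN libraries.

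The 10 named genes with the largest rise were all at 0 in both WT_chow libraries, which allows 0.0507 CPM. They were 4 mitochondrial transfer RNA genes of the minus strand, mt-Te, mt-Tq, mt-Ts1 and mt-Ty, and 6 nuclear genes that each overlap an exon on the opposite strand. Serinc4 (opposite Hypk and Serf2) reached 410 ± 39.1 CPM in NASH_GAN, at least 7980-fold higher (adjusted p = 3.5e-05). Mir135a-1 (opposite Glyctk) reached 290 ± 48.1 CPM, Msmp (opposite Rgp1) 240 ± 35.0 CPM and Tctex1d4 (opposite Plk3) 176 ± 51.8 CPM. Kpna7 (opposite Arpc1a) and Lrrc14b (opposite Ccdc127) reached 147 ± 7.93 and 136 ± 35.7 CPM. The transfer RNA gene mt-Te reached 2817 ± 2823 CPM, with 5635 and 676 counts, an SD as large as the mean. Counts of mt-Tq were 1919 and 42, of mt-Ts1 1603 and 16, and of mt-Ty 1360 and 180. Calls of mt-Tq and mt-Ts1 were lost without either WT_chow library (adjusted p from 0.30 to 0.40). The 10 named genes with the largest fall were all at 0 in both NASH_GAN libraries, against a floor of 1.505 CPM. Clpx, a mitochondrial chaperone, was at 219 ± 4.70 CPM in WT_chow and at least 145-fold lower in NASH_GAN (adjusted p = 9.9e-05), and the cell surface proteoglycan gene Sdc2, at 213 ± 3.38 CPM, was at least 142-fold lower. Klhl24 was at least 107-fold lower, Pm20d1 at least 94.8-fold, the phosphatase gene Ppp1cb at least 87.6-fold, and Pdia6, Sec23a and the cytochrome oxidase gene Cox8a at least 85.4-fold, 85.3-fold and 85.0-fold. Slc22a30 and Cyp2c68 were at least 194-fold and 117-fold lower, but 35.9% and 43.3% of their 50-base words occur in another gene, so their levels are uncertain. Of these 10, Pdia6 (opposite Atp6v1c2) and Sec23a (opposite Gm17529) have an opposite-strand exon.

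Hepatocyte genes were counted lower almost throughout. Here and in all lists below, higher and lower refer to the deposited counts. Because NASH_GAN counts followed the opposite gene across overlapping genes, as given above, a lower count need not mean less transcript in that pool. All 20 measured hepatocyte secretory and identity genes were lower, with a median log2 change of -4.63 that lay at percentile 0.23 of 10000 random lists of the same size and expression. This standing was lost without NASH_GAN replicate 1, where the list lay at percentile 12.1, or 11.25 with genes at 0 in the matched lists at their bound. Alb was at 85403 ± 7902 CPM in WT_chow and 1081 ± 96.6 CPM in NASH_GAN (log2 change -5.70 ± 0.45, adjusted p = 1.1e-04). Apob, the structural protein of very low density lipoprotein, was at 19457 ± 406 against 282 ± 77.4 CPM, and Tat, tyrosine aminotransferase, at 1153 ± 25.7 against 7.35 ± 6.78 CPM. For Apoc3 the levels were 486 ± 46.9 and 5.53 ± 4.199 CPM. Of these 20 genes, 3 have an opposite-strand exon. Of 14 pericentral hepatocyte genes 13 were lower and 1 did not pass (median -3.86, percentile 15.2, or -3.61 at the bound, percentile 7.45), among them Cyp1a2 (255 ± 14.2 against 5.85 ± 1.40 CPM), Oat (258 ± 17.9 against 6.21 ± 1.53 CPM) and Rgn (604 ± 25.4 against 2.56 ± 3.62 CPM). Of 15 periportal genes 13 were lower and 2 did not pass (median -4.09, percentile 8.12, or 4.87 with genes at 0 in the matched lists at their bound), among them the urea cycle genes Cps1 (5755 ± 124 against 62.2 ± 20.3 CPM) and Arg1 (1001 ± 0.804 against 19.2 ± 5.44 CPM). Without either WT_chow library both lists lay below percentile 2.5 at the bound (pericentral 1.13 and 1.28, periportal 0.335 and 0.365), and the periportal list also with fitted values (1.12 and 1.28). Ribosomal protein genes, used by every cell type, showed a median log2 ratio of -3.41 over 59 genes without an opposite-strand exon (upper quartile -2.86). These ratios used library totals, not the TMM scale of the list medians. On the TMM scale, all 11248 tested genes without such an exon had a median log2 change of -3.51.

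Kupffer cells are the resident macrophages of the liver, and 12 of 18 measured genes of their identity were counted lower, 3 higher and 3 did not pass. The fitted median log2 change was -3.01, at percentile 48.2 of matched lists. With genes at 0 in NASH_GAN set to their bound, 2 members among them, it was -2.44 at percentile 40.6. It was -4.91 without NASH_GAN replicate 1, or -2.63 at the bound. Clec4f, a Kupffer cell lectin, was at 73.3 ± 2.08 CPM in WT_chow and 2.14 ± 3.02 CPM in NASH_GAN (5 and 0 counts). Adgre1, which encodes the F4/80 antigen, had 1 count in NASH_GAN against 904 and 867 in WT_chow, a 59.7-fold lower share with a 95% counting interval of 10.7 to 2359. Timd4 was at 0 in NASH_GAN and at least 7.31-fold lower, and Spic at least 1.84-fold lower. The call of Timd4 was lost without WT_chow replicate 2 (adjusted p = 0.051) and that of Spic without WT_chow replicate 1 (0.21) or 2 (0.23). C6, which hepatocytes also express, had 1 count against 6428 and 6414 (433-fold lower, counting interval 77.7 to 17099). The higher members were Il18bp (22.2 ± 1.05 CPM in WT_chow, 32.5 and 35.2 CPM in NASH_GAN), Folr2 (6.75 ± 0.027 CPM, 18.8 and 12.1 CPM) and Cd163 (13.6 ± 0.902 CPM, 30.8 and 19.4 CPM), and Il18bp and Folr2 have an opposite-strand exon. By mean CPM alone Il18bp and Cd163 were less than 2-fold higher. Here and below, higher members outside the naming rule are given because they were few and were chosen after their values were seen.

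Genes of lipid-associated macrophages, which accumulate around lipid-laden hepatocytes and scars, gave 11 lower, 1 higher and 6 not passing among 18 measured. Their fitted median log2 change was -3.36, at percentile 19.03. With genes at 0 set to their bound, 5 members among them, it was -2.65 at percentile 0.06. Fitted on genes without an opposite-strand exon alone, the median of 15 members was -1.56, at percentile 65.6, against -2.81 for the same members in the fit on all genes. Without NASH_GAN replicate 1, where 12 members were at 0, the fitted median was -8.21 (percentile 0.42) and the median at the bound -1.18 (percentile 9.25), so the list did not stand apart in every treatment. Trem2, the receptor that marks these cells, was at 17 and 28 counts in WT_chow and 1 and 0 in NASH_GAN, and did not pass (log2 change -0.05 ± 1.43, adjusted p = 0.98; positive with upper quartile scaling). Gpnmb was at 31 and 27 counts against 0 and 0 and did not pass (adjusted p = 0.14); both groups lay under the NASH_GAN floor, so no fold was given. Spp1, which encodes osteopontin, was at 12.7 ± 0.861 against 1.46 ± 0.349 CPM, an 8.47-fold lower share (counting interval 2.89 to 41.2) from 3 counts. Cd9 was at 0 in NASH_GAN and at least 5.33-fold lower, Fabp5 at least 32.8-fold and Atp6v0d2 at least 13.1-fold. Cd9 has an opposite-strand exon, in Gm26728. The calls of Spp1 and Cd9 were lost without WT_chow replicate 1 (adjusted p = 0.24 and 0.084) or replicate 2 (0.21 and 0.076). The chemokine gene Ccl3 was the higher member, with 0.372 ± 0.051 CPM in WT_chow and 12.8 and 2.43 CPM in NASH_GAN.

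Of 8 monocyte genes 5 were lower and 3 did not pass (median -7.74, percentile 2.07, or -0.38 at the bound, percentile 25.6). The fitted percentile was above 2.5 when any 1 library was left out (13.8 and 16.5 without the WT_chow replicates, 5.93 and 2.87 without the NASH_GAN replicates). Ccr2, the chemokine receptor of inflammatory monocytes, was at 3.37 ± 0.432 CPM in WT_chow and 0 in NASH_GAN, at least 2.24-fold lower, Sell at least 4.33-fold and Plac8 at least 2.75-fold. The integrin gene Itgam was at least 1.56-fold lower, with 72.4% of its words shared with another gene. These calls were lost without WT_chow replicate 1 or 2 (adjusted p from 0.10 to 0.25), and that of Itgam also without NASH_GAN replicate 2 (0.060). Of 2 measured neutrophil genes, Csf3r was at least 2.81-fold lower and the other did not pass (median -7.87, or -0.46 at the bound; call lost without WT_chow replicate 1 or 2, adjusted p = 0.15 and 0.17). Dendritic cell and MHC class II genes gave 4 higher, 4 lower and 6 not passing among 14 (median -0.93, percentile 78.0, or -0.48 at the bound, percentile 44.6). Clec9a, a receptor of cross-presenting dendritic cells, was at 6.43 ± 0.765 CPM in WT_chow and 34.7 ± 11.3 CPM in NASH_GAN, Itgae at 0.677 ± 0.244 and 4.75 ± 1.88 CPM, and H2-Aa at 48.4 ± 1.48 and 1.28 ± 1.81 CPM, from 3 counts (32.2-fold lower, counting interval 11.0 to 156). The call of Itgae was lost without WT_chow replicate 1 (adjusted p = 0.19) or 2 (0.12) and without NASH_GAN replicate 2 (0.058). Xcr1 and the MHC class II transactivator Ciita, which has an opposite-strand exon in Dexi, were the other higher members. Clec9a lies within 5 kb of Clec1a on the opposite strand. Of 10 T and NK cell genes 1 was higher and 9 did not pass (median 0.28, percentile 34.3, or 0.34 at the bound, percentile 28.5): the chemokine receptor gene Cxcr6 was at 5.07 ± 0.181 against 66.9 ± 10.5 CPM and lies within 5 kb of Fyco1 on the opposite strand. B cell and plasma cell genes gave 1 higher, 2 lower and 7 not passing of 10 (median -7.64, percentile 12.4, or -0.092 at the bound, percentile 65.1). Ighm was at least 9.37-fold lower and, with a call lost without WT_chow replicate 1 or 2 (adjusted p = 0.22 and 0.21), Ms4a1 at least 1.899-fold, while the kinase gene Blk was at 1.22 ± 0.631 against 24.6 ± 15.9 CPM. Single libraries moved these medians by over 1.5 times: without WT_chow replicate 1, the fitted median, with the one at the bound in brackets, was -7.15 (-0.61) for monocyte genes, 0.64 (0.80) for T and NK cell genes, at percentile 98.5 either way, and -7.12 (-0.25) for B cell genes. It was -0.11 (0) for T and NK cell genes and -6.86 (-0.19) for B cell genes without WT_chow replicate 2. It was -8.30 (-0.088) for monocyte genes, -8.28 (-0.25) for neutrophil genes, -5.57 (-0.12) for dendritic cell genes, -6.93 (0) for T and NK cell genes and -8.46 (0) for B cell genes without NASH_GAN replicate 1. It was -8.14 (0) for monocyte genes, -8.28 (-0.13) for neutrophil genes, -0.64 (0) for dendritic cell genes and -8.41 (0) for B cell genes without NASH_GAN replicate 2.

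Hepatic stellate cells store vitamin A when quiescent and make matrix when activated. Of 16 genes of the quiescent state 12 were counted lower, 1 higher and 3 did not pass, with a fitted median log2 change of -3.75 at percentile 19.2. With genes at 0 set to their bound, 3 members among them, it was -3.33 at percentile 1.04. Without NASH_GAN replicate 1, where 12 members were at 0, the fitted median was -11.16 (percentile 0.39) and the median at the bound -2.59 (percentile 11.2), so this list also did not stand apart in every treatment. Lrat, which esterifies retinol, was at 17.7 ± 0.465 CPM in WT_chow and 0 in NASH_GAN, at least 11.8-fold lower, and the growth factor gene Hgf was at least 14.7-fold lower. Dcn, which encodes decorin, was at 121 ± 10.3 against 2.14 ± 3.02 CPM. Des was at 66 and 97 counts against 1 and 0 and did not pass (log2 change -1.89 ± 1.10, adjusted p = 0.16). Angptl6 was the higher member, at 3.16 ± 0.239 against 130 ± 24.2 CPM, and has an opposite-strand exon in A230050P20Rik. Among 14 measured genes of activated stellate cells and myofibroblasts 9 were lower, 1 higher and 4 did not pass (median -2.07, percentile 73.0, or -1.29 at the bound, percentile 62.7). It was -7.26 without NASH_GAN replicate 1, or -1.23 at the bound, and at the bound without NASH_GAN replicate 2 it was -0.70. Col1a1, a chain of type I collagen, was at 19.2 ± 0.0236 against 1.71 ± 2.42 CPM (log2 change -2.71 ± 0.63, adjusted p = 0.0084), from 4 and 0 counts in NASH_GAN. Col3a1 was at 39.8 ± 1.88 against 2.32 ± 1.56 CPM, Lum with 184 and 172 counts against 0 and Fstl1 at least 3.26-fold lower. The calls of Col1a1, Lum and Fstl1 were lost without WT_chow replicate 1 (adjusted p = 0.13, 0.12 and 0.14) or replicate 2 (0.13, 0.11 and 0.14). Acta2, the smooth muscle actin of myofibroblasts, was at 4.09 ± 0.543 against 2.14 ± 3.02 CPM and did not pass (log2 change -0.17 ± 0.82, adjusted p = 0.86; positive with upper quartile scaling). Without NASH_GAN replicate 1 it was at 0 in NASH_GAN and passed (adjusted p = 0.015). Timp1, an inhibitor of matrix metalloproteinases, had 2 and 5 counts in WT_chow and 2 and 0 in NASH_GAN and was too low to test. Tagln was the higher member, at 4.78 ± 0.155 against 81.2 ± 8.37 CPM, and has an opposite-strand exon in Pcsk7.

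Other matrix genes gave 14 lower, 1 higher and 8 not passing of 23 (median -2.80, percentile 38.9, or -2.28 at the bound, percentile 2.08). Bgn was at 100.02 ± 0.614 against 2.14 ± 3.02 CPM and Col5a1 at least 10.4-fold lower, and Timp3, which has an opposite-strand exon and was less than 2-fold higher by mean CPM, was the higher member. Sinusoidal endothelial genes gave 15 lower and 1 not passing of 16 (median -4.07, percentile 10.3, or 5.79 with genes at 0 in the matched lists at their bound). Dnase1l3 was at 67.4 ± 2.23 against 1.03 ± 0.255 CPM, from 2 counts in NASH_GAN (67.2-fold lower, counting interval 18.6 to 555). F8, which encodes coagulation factor VIII, had 1 count against 1625 and 1807 (116-fold lower, counting interval 20.7 to 4571). Of 12 vascular endothelial genes 7 were lower and 5 did not pass (median -2.50, percentile 49.6, or -1.65 at the bound, percentile 2.69), with Vwf at least 2.96-fold and Efnb2 at least 3.12-fold lower, calls lost without WT_chow replicate 1 or 2 (adjusted p from 0.14 to 0.15). Cholangiocyte genes gave 3 lower and 3 not passing of 6 (median -3.64, percentile 33.5, or -0.59 at the bound, percentile 48.2). Pkhd1 was at 26.2 ± 1.44 against 1.03 ± 0.255 CPM and the bile duct transcription factor gene Sox9 at 13.1 ± 0.189 against 0.854 ± 1.21 CPM, each from 2 counts in NASH_GAN (26.2-fold lower, counting interval 7.23 to 216, and 13.04-fold lower, 3.60 to 108). The call of Sox9 was lost without WT_chow replicate 1 or 2 (adjusted p = 0.15 and 0.14). Krt19 was at 34 and 19 counts against 1 and 0 and did not pass (adjusted p = 0.87; log2 change -0.28 ± 1.44, positive with upper quartile scaling). Single libraries moved some of these medians: without NASH_GAN replicate 1, the fitted median, with the one at the bound in brackets, was -8.63 (-1.42) for matrix genes, at percentile 1.85 (21.5), -8.30 (-0.57) for vascular endothelial genes and -7.55 (-1.21) for cholangiocyte genes. It was -2.73 (-0.98) for vascular endothelial genes and -3.48 (-0.06) for cholangiocyte genes without NASH_GAN replicate 2.

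Lipid and sterol genes were mostly lower. Cholesterol synthesis genes gave 18 lower, 1 higher and 3 not passing of 22 (median -5.55, below all 10000 matched lists, or -4.97 at the bound, percentile 0.01). The list did not stand apart without NASH_GAN replicate 1, at percentile 5.81, or 16.9 at the bound. Hmgcs1 was at 468 ± 9.05 against 1.03 ± 0.255 CPM, from 2 counts in NASH_GAN (467-fold lower, counting interval 129 to 3856), Sc5d at 1083 ± 43.0 against 2.25 ± 1.97 CPM, and Nsdhl at least 54.7-fold lower. Sqle, squalene epoxidase, was at 94.0 ± 0.731 against 72.2 ± 12.7 CPM and did not pass (log2 change 0.20 ± 0.21, adjusted p = 0.41; -0.16 with DESeq2 size factors and -0.37 with total counts). Without NASH_GAN replicate 1 it was lower at -0.86 (adjusted p = 0.0017). Fdft1, which has an opposite-strand exon in Ctsb and was less than 2-fold higher by mean CPM, was the higher member. Fatty acid and triglyceride synthesis genes gave 16 lower and 2 not passing of 18 (median -4.66, percentile 0.68, or 0.13 with genes at 0 in the matched lists at their bound). This too was lost without NASH_GAN replicate 1, at percentile 56.8, or 27.9 at the bound. Scd1, stearoyl-CoA desaturase, was at 27604 ± 7.70 against 279 ± 148 CPM (log2 change -5.99 ± 0.62, adjusted p = 3.0e-04) and Elovl5 at 1506 ± 36.7 against 10.2 ± 1.08 CPM. Among 15 lipid droplet genes 8 were lower, 3 higher and 4 did not pass (median -2.50, percentile 64.0, or -2.43 at the bound, percentile 31.8). Plin2, the main coat protein of hepatocyte lipid droplets, was at 536 ± 28.7 against 17.2 ± 1.40 CPM, and Cidec, which promotes droplet growth, at 4.06 ± 0.461 against 27.9 ± 5.17 CPM. Plin4 and Cideb, the other higher members, have an opposite-strand exon, and Cideb was less than 2-fold higher by mean CPM. Cidea had 0 counts in all 4 libraries. All 21 fatty acid oxidation genes were lower (median -3.94, percentile 10.01, or 4.11 with genes at 0 in the matched lists at their bound), with Acox1 at 2757 ± 79.0 against 64.9 ± 26.6 CPM. Bile acid and sterol transport genes gave 16 lower and 1 higher of 17 (median -4.05, percentile 7.14, or -4.04 at the bound, percentile 4.71). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 69.0 ± 4.08 CPM in WT_chow and had 1 count in NASH_GAN (138-fold lower, counting interval 24.7 to 5437), and the bile salt export pump gene Abcb11 was at 972 ± 22.2 against 9.60 ± 8.75 CPM. Abcg8, which has an opposite-strand exon and was less than 2-fold higher by mean CPM, was the higher member. Xenobiotic metabolism genes gave 16 lower and 1 not passing of 17 (median -4.90, percentile 0.70, or -3.36 at the bound, percentile 7.67), with Cyp2c70 at 423 ± 15.8 against 2.07 ± 0.509 CPM. Xenobiotic genes lay at fitted percentile 5.775 and 4.44 without NASH_GAN replicate 1 and 2, and at 0.85 at the bound without WT_chow replicate 1. Without either WT_chow library, fatty acid oxidation and bile acid genes lay below percentile 2.5 (2.30 and 1.93, and 1.345 and 1.13; at the bound 0.57 and 0.565, and 0.76 and 0.63). The median of lipid droplet genes was -4.46 without NASH_GAN replicate 1, or -3.01 at the bound.

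Cytokine, chemokine and adhesion genes gave 6 lower, 1 higher and 5 not passing of 12 (median -2.18, percentile 48.9, or -0.88 at the bound, percentile 39.6), with Icam1 at least 5.43-fold lower (call lost without WT_chow replicate 1 or 2, adjusted p = 0.078 and 0.077) and Cxcl16, which has an opposite-strand exon, higher. Interferon response genes gave 11 lower, 1 higher and 4 not passing of 16 (median -3.44, percentile 24.1, or -2.06 at the bound, percentile 28.0), with Rsad2 at least 12.9-fold lower and Usp18 higher. Of 20 cell cycle genes 10 were lower, 3 higher and 7 did not pass (median -3.42, percentile 20.8, or -1.11 at the bound, percentile 44.0). The helicase gene Mcm6 was at least 7.83-fold lower, and Ccna2, Ccne2 and Tk1, each with an opposite-strand exon, were higher. Genes of the unfolded protein and integrated stress responses gave 12 lower, 1 higher and 2 not passing of 15 (median -3.94, percentile 14.005, or -3.59 at the bound, percentile 2.04), with Dnajb9 at least 68.3-fold lower and Ddit3, with an opposite-strand exon, higher. Acute phase genes gave 8 lower and 7 not passing of 15 (median -3.16, percentile 27.4, or 0.56 with genes at 0 in the matched lists at their bound), with Hpx at 2082 ± 305 against 55.0 ± 26.2 CPM. Of 9 oncofetal genes 2 were higher, 2 lower and 5 did not pass (median -7.00, percentile 9.69, or 0 at the bound, percentile 68.9). The fetal serum protein gene Afp was at 3.72 ± 0.745 against 59.5 ± 1.67 CPM and Igf2bp3, opposite Malsu1, at 1.91 ± 0.0382 against 52.3 ± 15.5 CPM. Immediate early and heat shock genes gave 8 lower and 4 not passing of 12 (median -2.16, percentile 72.0, or 40.3 with genes at 0 in the matched lists at their bound), with Zfp36 at 132 ± 3.43 against 6.09 ± 3.46 CPM. Among these lists, without NASH_GAN replicate 1, the fitted median, with the one at the bound in brackets, was -5.99 (-0.61) for cytokine genes, -10.40 (-1.59) for interferon genes, -9.03 (-0.58) for cell cycle genes, -10.09 (-2.48) for stress response genes, at percentile 1.40 (20.7), and -6.13 (-3.33) for acute phase genes, at percentile 30.5 (4.015). It was -4.97 (-0.20) for cytokine genes and -5.52 (-0.61) for cell cycle genes without NASH_GAN replicate 2.

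Of 14 circadian clock genes 9 were lower, 1 higher and 4 did not pass (median -2.37, percentile 66.8, or -2.35 at the bound, percentile 30.6), with Nfil3 at least 11.1-fold lower and Ciart higher. Male-biased liver genes gave 10 lower and 2 not passing of 12 (median -5.80, percentile 0.05, or -4.85 at the bound, percentile 0.30; at the bound 31.95 without NASH_GAN replicate 1 and 3.47 without replicate 2, where fitted values gave 2.19 and 0), with Elovl3 at least 36.7-fold lower. Female-biased genes gave 2 lower and 4 not passing of 6 (median -1.87, percentile 63.4, or -0.38 at the bound, percentile 79.2), with Cux2 at least 2.51-fold lower (call lost without WT_chow replicate 1 or 2, adjusted p = 0.19 and 0.16). Of 5 sex chromosome genes the 4 on the Y chromosome were lower and Xist, which has an opposite-strand exon, was higher (median -5.31, percentile 6.42, or -5.21 at the bound, percentile 0.45). At the bound the list lay at percentile 5.54 without NASH_GAN replicate 1 and 9.75 without replicate 2, where its fitted percentile was 0.43. Ddx3y had 2853 and 2981 counts in WT_chow and 1 and 0 in NASH_GAN (197-fold lower, counting interval 35.3 to 7769). Erythroid and platelet genes gave 4 lower and 1 not passing of 5 (median -10.44, percentile 0.53, or -2.61 at the bound, percentile 46.0; fitted percentile 5.38 without NASH_GAN replicate 1), all 4 of them globin genes with at least 58.3% of their words in another gene. The calls of Hba-a2 and Hbb-bt were lost without WT_chow replicate 1 (adjusted p = 0.071 and 0.084), NASH_GAN replicate 1 (0.15 and 0.11) or NASH_GAN replicate 2 (0.16 and 0.13). Of the pancreas, adipose and mesothelium genes, 1 was measured and it did not pass (log2 change 0.30). Over all 36 lists, 479 different genes were measured, of which 325 were lower, 29 higher and 125 did not pass, and 18 of the 29 higher genes have an opposite-strand exon, against 2509 of 4304 over all higher genes. Of the higher members named by the rule, Afp, Blk, Cidec and Itgae have neither such an exon nor a neighbour on the opposite strand as defined above. Fitted medians of 7 lists lay below the central 95% of matched lists, and 0 lay above it, but fitted values of genes at 0 counts are not measured folds. With such genes at their bound 10 lists lay below it, of which 4 did so in both treatments: hepatocyte secretory and identity genes, cholesterol synthesis, fatty acid and triglyceride synthesis and male-biased genes. At the bound alone, the lipid-associated macrophage, quiescent stellate, matrix, stress response, acute phase and sex chromosome lists did so. With fitted values alone, the monocyte, xenobiotic and erythroid lists did. Without 1 library, lists below it at the bound numbered 16 (WT_chow replicate 1, with 1 list above), 14 (WT_chow replicate 2), 0 (NASH_GAN replicate 1) and 8 (NASH_GAN replicate 2). The random lists were not matched on opposite-strand exons. Such an exon was present in 3 of 20 hepatocyte secretory and identity genes and 4 of 22 cholesterol synthesis genes. It was present in 4 of 18 fatty acid and triglyceride synthesis genes and 2 of 12 male-biased genes, against 4967 of 16353 tested genes. The low percentiles of these 4 lists cannot be told apart from this difference. Of lists low at the bound alone, 0 of 15 acute phase, 3 of 18 lipid-associated macrophage and 3 of 15 stress response genes had such an exon. It was present in 5 of 23 matrix, 1 of 5 sex chromosome and 6 of 16 quiescent stellate genes. With fitted values alone these were 1 of 8 monocyte, 3 of 17 xenobiotic and 1 of 5 erythroid genes. Except for quiescent stellate genes, these lists share the limit. Adjusted over the list alone, the counts changed for 4 lists: 3 lower for dendritic cells, 1 lower for B cells, 6 lower for vascular endothelium and 11 lower for male-biased genes. Leaving out libraries moved medians here too: without WT_chow replicate 1, the fitted median, with the one at the bound in brackets, was 0.49 (0.49) for the pancreas, adipose and mesothelium list. It was 0.068 (0.068) for this list without WT_chow replicate 2. It was -9.79 (-1.09) for female-biased genes and -7.58 (0) for this list without NASH_GAN replicate 1. It was -1.19 (-0.049) for female-biased genes, -9.03 (-4.47) for male-biased genes, -12.80 (-3.98) for sex chromosome genes and 0.98 (0.98) for this list without NASH_GAN replicate 2.

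The libraries of a pool did not vary alike. The biological coefficient of variation, here a technical one, was 16.2% between the WT_chow libraries and 44.3% between the NASH_GAN libraries. Both pairs differed beyond sampling noise, with a chi-square of 21.5 and 34.3 per degree of freedom. Within NASH_GAN, the replicates were compared through the genes opposite to list members. For 25 hepatocyte list members the log2 ratio of replicate 1 to replicate 2, centred on all 2395 genes, averaged -1.04 ± 1.26 (SD), with 20 below 0. For 22 members of lists of other cell types it averaged 0.42 ± 1.13, with 16 above 0. These means differed by 1.47 (95% bootstrap interval 0.82 to 2.15; two-sided permutation test, p = 0.00024, adjusted p = 0.00072 over 3 comparisons). This p-value is over genes of 2 libraries, genes are not independent replicates, and the grouping of lists was written after the data were seen. In WT_chow the same genes differed by -0.046 (interval -0.14 to 0.057; permutation p = 0.38, adjusted p = 0.57). The counts opposite Cyp2f2 were 5214 and 16339, opposite Me1 260 and 1456, and opposite Acss2 342 and 1149. In the other direction, counts opposite Ciita were 138 and 21, opposite Col5a1 83 and 13, and opposite Fbn1 22 and 2.

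**Figure D3:**
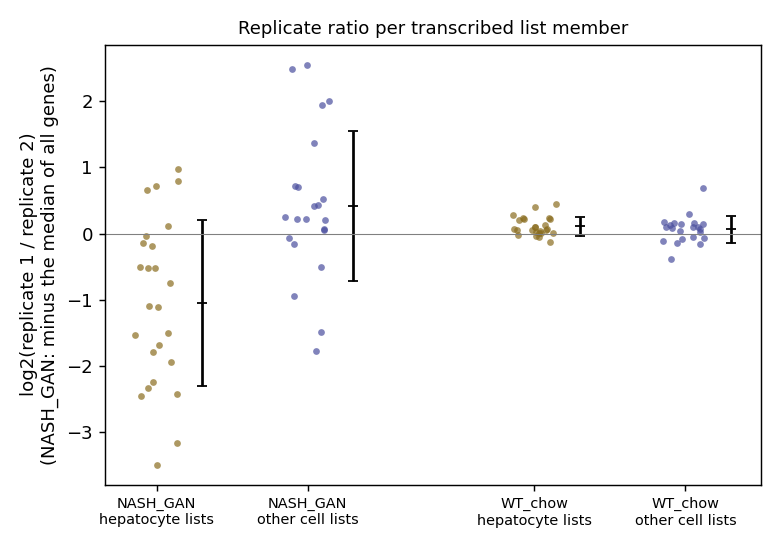
Each point is a list member, with the log2 ratio of replicate 1 to replicate 2 on the vertical axis, read from the opposite-strand gene in NASH_GAN (minus the median of all genes) and from the gene itself in WT_chow. Bars are mean ± SD. Hepatocyte members average -1.04 and members of other cell types 0.42 in NASH_GAN, while in WT_chow these averages are 0.11 and 0.065.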

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

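The fits on genes with or without an opposite-strand exon and the medians at the bound, with all libraries or without 1, were chosen after the data were seen; the others were planned. The median over all tested genes was -2.50 in the main fit, -1.57 with upper quartile scaling and -0.307 on log2(TPM + 1), or 0 with no filter. A negative list median therefore does not by itself set a list apart from other genes. List medians were not taken with the other fold thresholds. Except as given below, they were not taken from fits on genes with a count in every library or with an opposite-strand exon. In each alternative that gave them, medians of the Kupffer, lipid-associated macrophage, quiescent and activated stellate lists were negative. Their size changed: on log2(TPM + 1) they were -0.73, -0.51, -0.51 and -0.31 (the last -0.22 with no filter), on log2(TPM + 0.1) the Kupffer and quiescent stellate medians were -1.85 and -2.32, and with upper quartile scaling that of activated stellate genes was -1.13. Fitted on genes without an opposite-strand exon they were -2.42, -1.56, -2.93 and -2.18, against -3.66, -2.81, -4.17 and -3.43 for the same members in the fit on all genes, and the lipid-associated macrophage list lay at percentile 65.6. The 4 Kupffer and 5 activated stellate members with such an exon had medians of 0.80 and 0.82 in the fit on all genes, and -1.81 and -1.77 fitted on genes with one. Counts of higher and lower genes moved beyond 1.5 times in these cases: 4476 and 4569 lower without WT_chow replicate 1 and 2, 1976 higher and 4828 lower on log2(TPM + 1), and 2858 higher on log2(TPM + 0.1), where lower genes numbered 8879 and higher genes made up 24.4% of calls against 34.4%. Fits on part of the genes test fewer genes and are set beside the fit on all genes over the same genes. With a count in every library, 3152 were higher and 4176 lower, against 3882 and 3333. Without an opposite-strand exon these numbers were 1940 and 4047, against 1742 and 6658, and with one 1817 and 2453, against 2509 and 1502. Among these, the lower counts of the last pair of sets moved beyond 1.5 times. Medians turned from 0.43 to -1.03 for genes with a count in every library and from 1.41 to -1.20 for those with an opposite-strand exon; scale factors and dispersions are re-estimated within each set. The cause was not tested. On log2(TPM + 1) with no filter limma called 0 higher and 0 lower genes, with 7649 genes at an unadjusted p under 0.05; the DESeq2 Wald test called 4097 and 8676, of which 4086 and 8166 were also called by edgeR. Leaving out 1 library gave 3096 to 4209 higher and 4476 to 9276 lower genes; the lone library is then assumed to vary like the other group. Without NASH_GAN replicate 1 the median of the lipid-associated macrophage list was -8.21 and of the quiescent stellate list -11.16, fitted values that rest on members at 0; at the bound they were -1.18 and -2.59 and did not stand apart. Over the 4 omissions the fitted medians spanned -8.21 to -3.38 and -11.16 to -3.50. With all libraries and genes at 0 at their bound, the medians of these lists were -2.65 (percentile 0.06) and -3.33 (percentile 1.04), and without the WT_chow replicates and NASH_GAN replicate 2 -2.63, -2.71 and -2.13, and -3.27, -3.47 and -2.67. With the DESeq2 Wald test the quiescent stellate median was -4.12 at percentile 2.05. The cause was not tested.

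The replicate numbers mark technical splits and share only a number: same-numbered deviations correlated at 0.0019 over 16353 genes and -0.10 over 3736 genes with at least 20 counts per group. With a replicate block 3850 genes were higher and 6250 lower, and the 4 list medians were -3.13, -3.40, -3.96 and -2.23.

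For named genes, 2062 values kept their side of the threshold, 424 lost the call, 5 gained it and 23 changed sign, the last for 4 genes that were not called. More named genes lost the call without a WT_chow replicate than without a NASH_GAN replicate, where the spread comes from the tighter WT_chow pair. The call was lost by 153 on log2(TPM + 1) without a filter and 65 with one, 33 without opposite-strand exons, 25 with the replicate block, 19 on log2(TPM + 0.1), 15 with upper quartile scaling, 6 with at least 10 counts and 2 with no filter. Sqle changed sign with DESeq2 size factors (-0.16), total counts (-0.37), no filter (-0.80), the DESeq2 Wald test (-0.16), log2(TPM + 1) (-0.69 with and without a filter), log2(TPM + 0.1) (-1.16) and without NASH_GAN replicate 1 (-0.86). Acta2, Krt19 and Trem2 became positive with upper quartile scaling (0.76, 0.65 and 0.88), at least 10 counts (0.32, 0.20 and 0.44), without NASH_GAN replicate 2 (0.52, 0.39 and 0.62) and without opposite-strand exons (1.10, 0.97 and 1.20). Krt19 was 0.18 without WT_chow replicate 1, and Trem2 0.33 without WT_chow replicate 2 and 0.011 with the replicate block. Over the 4 omissions Acta2 spanned -9.36 to 0.52, Krt19 -7.18 to 0.39, Trem2 -6.94 to 0.62 and Sqle -0.86 to 0.25. The cause was not tested. Depth limits the NASH_GAN side: 1 count there is a large step for every gene near the floor of 1.505 CPM.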

Other observations

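All tests below except the one on shared sequence were chosen after the result was seen. Between the NASH_GAN libraries, some genes opposite to lipid synthesis, circadian and immediate early genes had more counts in replicate 2: opposite Jun 195 and 735, opposite Nr1d1 204 and 572, opposite Pklr 2272 and 3009, and opposite Srebf1 164 and 295. Others had more in replicate 1: opposite Cxcl16 278 and 59, opposite Ms4a6c, a monocyte gene, 455 and 82, opposite Hexb 547 and 131, and opposite Sox4 264 and 30. These genes were picked by their ratio. Among the members that went against their list group's mean were Glul, a hepatocyte gene, at 2369 and 754, and the Kupffer gene Fcna at 182 and 387. For 14 members of other cell type lists and 19 hepatocyte members with an estimate, the NASH_GAN level over the WT_chow prediction differed by -0.078 log2 units (95% bootstrap interval -1.61 to 1.51, permutation p = 0.92, adjusted p = 0.92), and its SD over 1637 genes was 1.62. With an interval this wide, the test could not decide whether the NASH_GAN pool held a higher share of non-hepatocyte RNA.

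The first pattern is the placement of NASH_GAN counts opposite to transcribed genes. Random thinning keeps each gene's expected share, so thinning WT_chow to the NASH_GAN depths could not test lower depth as a cause. It put at most 22.2% of counts on genes with an opposite-strand exon, against 74.4% and 78.2% in NASH_GAN. If loss of hepatocyte transcripts with the diet were the whole cause, ribosomal protein genes would keep their share. Their upper quartile log2 ratio was -2.86. These were, however, taken only from genes without an opposite-strand exon, whose median over 11248 tested genes was already -3.51 on the TMM scale. Their fall is thus not separate from that of this class, and the test could not decide on this cause. A candidate explanation is that the NASH_GAN files were counted on the strand opposite to the transcripts, with a lowest rho of 0.657 to the opposite gene; the kit named in the labels makes stranded libraries, so such a setting is possible, and the strand setting is not given in the sources used here. Under this hypothesis the calls of the comparison would not measure the diet, and any diet effect remains open because every NASH_GAN library and no WT_chow library shows the pattern.

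The second pattern is the spread between the NASH_GAN libraries. Counting noise of independent reads as the whole cause is argued against by a chi-square of 34.3 per degree of freedom between the NASH_GAN libraries. The thinned WT_chow pair cannot decide this, since its coefficient of variation, at most 0.105 against 0.443, leaves counting noise out. Mitochondrial content as the whole cause is argued against by a coefficient of 0.431 without mitochondrial genes. A difference in the make-up of hepatocyte and other RNA may contribute, with a difference of 1.47 log2 units between list groups written after the data were seen, over genes that are not independent. The shift was not shared by all hepatocyte lists. Against a hepatocyte mean of -1.04, with 20 of 25 members below 0, the pericentral members Tbx3, Slc1a2, Axin2 and Glul lay at -0.18, -0.14, 0.66 and 0.97. Of the 22 other members 16 lay above 0, while sinusoidal Gpr182 and Clec4g lay at -1.49 and -0.94. The labels describe 1 pool split into technical replicates, so no biological explanation was tested. Satellite-like Gm10800, at 3681 and 3 counts, also differed.

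The third pattern is the difference between the WT_chow libraries at 88 of 8294 genes with at least 500 counts. Shared sequence is consistent with it: 58.0% of the 88 hold at least 50% of their 50-base words in another gene, against 1.54% of the others (odds ratio 87.8, 95% interval 54.3 to 143), for example Gm7336 at 0 and 1569 counts and Mup12 at 44 and 1251. Size selection may add to it, as genes under 300 bases made up 37.0% of the 27 higher in replicate 1 and 3.28% of the 61 higher in replicate 2 (odds ratio 16.7, interval 3.13 to 171). Hspa9-ps1, at 1435 and 31 counts with 6.53% shared words, is covered by neither. No biological explanation was tested, since both libraries come from 1 pool.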
